A study of Mus musculus with 12 samples.

How the data were processed

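RNA was measured in cultured mouse fibroblast-like synoviocytes, the connective tissue cells of the joint lining, taken from mice described as SoxC. The 12 libraries form 4 groups of 3: control cells given an adenovirus carrying eGFP (control), the same with TNF (control_TNF), cells given an adenovirus carrying Cre recombinase (SoxC_KO), and the same with TNF (SoxC_KO_TNF). TNF was the recombinant human protein at 10 ng/mL for 16 h. Per the labels' protocols, RNA was extracted with Trizol, enriched for poly(A) and sequenced as paired reads on a NovaSeq. Groups and replicate numbers came from the sample titles. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. The part of each gene that Cre removes is not given in the sources used here.

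The deposited table holds 1 value per gene and library on the log2 scale, for 53341 genes. Per the file headers the values are normalized, and per the submitters' processing notes the genome build was mm10 and DESeq was among the tools. The aligner, the gene annotation and whether counting used strand are not given in the sources used here. The deposited log2 values carry no added pseudocount, and values at or under 1 normalized read are listed as 0. The design fixed before the data were examined assumed normalized values on a linear scale, so the deposited values were raised to the power of 2 (0 kept as 0) before the fixed transformation was applied. Of the 53341 gene identifiers, 53236 (99.8%) were found in the reference annotation, and 96.3% of those had the same start and end there. No gene of the mitochondrial chromosome was in the table used, and the fixed list of such genes was not analysed here.

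Normalized totals were 19.6 to 23.1 M per library. The commonest low value in each library was read as 1 read pair, which puts the total at 8.14 to 13.7 M read pairs. This estimate is rough. Only 52.4% to 59.1% of low values were whole or mid-step multiples of it, with a tolerance of 0.01 step, so whole reads were not recovered and no count model was run. Shallower libraries carry more counting error in low genes.

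Analysis used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with a normalized count of at least 10 in at least 3 of the 12 libraries were kept (18139 genes). Values were analysed as log2(normalized count + 1), so fold changes of low genes are understated. A limma model with 1 mean per group was fitted to all 12 libraries, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment over the genes kept, at a threshold of 0.05. The contrasts were TNF in control cells, TNF in knockout cells, knockout without TNF, knockout with TNF, their interaction, and the average TNF effect. The average knockout effect was added after the data were seen. Single SOXC genes were also compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3.

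Before the data were examined 32 gene lists were fixed, of which 31 had at least 2 genes tested. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists within each comparison. Fry tests whether a list's genes move on balance in 1 direction and does not set the list against other genes. Named genes were fixed by rule as up to 10 genes per direction with the largest change among those with adjusted p under 0.05, a mean of at least 50 in the higher group and no overlap between the groups' libraries, without clone names or pseudogenes. Sox4, Sox11 and Sox12 were always named, as were up to 4 called members of each list and, for a list with none, its member with the highest mean, of which some are left out for length. With no interaction gene passing, the 5 with the smallest p in each direction were taken, with the same limits on level and name, which the rule as fixed did not spell out for this case. Any other name is marked as chosen after its values were seen.

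Pairing by replicate number was checked on the correlation of same-numbered libraries after the group means were removed. Every pair exceeded 0.1 for control against control_TNF (r = 0.103, 0.550 and 0.715), for SoxC_KO against SoxC_KO_TNF (0.340, 0.148 and 0.501) and for control against SoxC_KO (0.457, 0.515 and 0.707). For control_TNF against SoxC_KO_TNF the values were 0.0537, 0.189 and 0.526, so at the cutoff of 0.1 these numbers were not read as pairs. Numbers that pair in the other comparisons would also pair here, so this split rests on the cutoff (0.103 passed, 0.0537 did not). The libraries numbered 3 stood apart in every group. With group means removed, this alone pushes the numbers 1 and 2 to correlate across groups. The check therefore cannot tell true pairs from that shared difference. Control replicate 1, SoxC_KO replicate 1 and SoxC_KO_TNF replicates 1 and 2 correlated best with another number. For the first 3 comparisons, and for the average TNF effect, which combines the first 2, the values with replicate number as a block are printed where they change a camera call or the number of genes called, with the member counts of the lists described.

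The model was tested on simulated values for 18139 genes with 200 changed genes, drawn with each gene's residual spread but with independent genes and libraries. The changed genes were picked only from those averaging at least 50 normalized counts on the log2 scale, so the rates do not cover lower genes. Each rate comes from 1 simulated draw. For TNF in control cells it recovered 25% of 2-fold and 73% of 4-fold changes, for knockout without TNF 29% and 73%, for knockout with TNF 16% and 70%, for the interaction 4% and 30%, and for TNF in knockout cells 16% and 59%. For the average TNF effect it recovered 47% and 88%, with 17 false calls, 11.2% of all calls, above the 5% aimed at. A simulated shift of 1 in the chemokine list for TNF in control cells was recovered, and 1 of the 30 other lists passed by chance. Genes were independent in this simulation, so it does not test the preset correlation. In the real data other splits of the same libraries also gave list calls. Alternatives included other pseudocounts, filters, scalings, variance models, library weights, the replicate block and leaving out each library. Alternatives chosen after seeing the data were a correction for transcript length and GC content (4 spline degrees of freedom each, 99.9% of genes tested having values), a term for the libraries numbered 3, leaving those 4 out, leaving out 2 libraries with liver transcripts, and the deposited log2 values without back-transformation.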

Results

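The series asks which parts of the TNF-regulated transcriptome of fibroblast-like synoviocytes depend on SOXC, the group of transcription factors made up of Sox4, Sox11 and Sox12. Poly(A) RNA was sequenced from 12 libraries in 4 groups of 3, control and SoxC knockout cells without and with TNF, an inflammatory cytokine. Normalized totals were 19.6 to 23.1 M per library, with an estimated 8.14 M (SoxC_KO_TNF replicate 1) to 13.7 M (control_TNF replicate 2) read pairs. No 2 libraries held identical values. The first principal component, with 51.6% of the variance, set the 4 libraries numbered 3 apart, 1 from each group. Liver transcripts stood out in control_TNF replicate 2 and SoxC_KO_TNF replicate 1, where albumin (Alb), named after its values were seen, was at 382 and 2690 normalized counts, against 7.54 or less in the other 10 libraries.

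**Figure D1:**
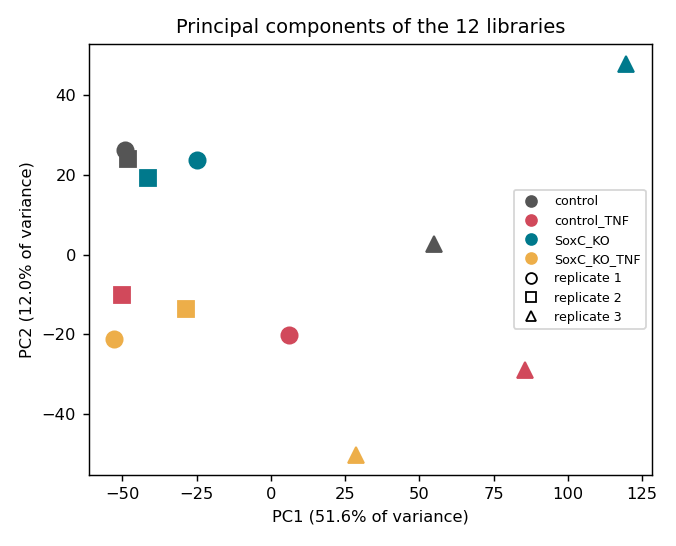
Scores of the 12 libraries on the first 2 principal components of log2(normalized count + 1). Colour gives the group and shape the replicate number, and PC1 (51.6% of variance) separates the libraries numbered 3 while PC2 holds 12%.

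Sox4 was lowest in the knockout groups. Its normalized count was 3413 ± 1348 in control, 2323 ± 1146 in control_TNF, 1138 ± 511 in SoxC_KO and 902 ± 263 in SoxC_KO_TNF (SD, n = 3 each), so knockout cells held 33.3% of the control level without TNF and 38.9% with it. All 3 knockout libraries lay below all 3 controls in both settings (exact permutation test, two-sided p = 0.1, the smallest 3 against 3 allow). Sox11 (chromosome 12, 27334264 to 27342574) averaged 232 ± 67.8 in control and 120 ± 80.9 in SoxC_KO, and 193 ± 54.6 in control_TNF and 69.7 ± 37.8 in SoxC_KO_TNF (SD, n = 3 each), with exact permutation p = 0.3 and p = 0.1. The exact tests ignored replicate number. Taken by number, Sox11 without TNF was 269, 272 and 153 in control and 175, 157 and 26.8 in SoxC_KO, lower for each number. Sox12 (chromosome 2, 152393611 to 152398063) averaged 285 ± 107 in control, 227 ± 32.6 in SoxC_KO, 281 ± 44.6 in control_TNF and 125 ± 36.5 in SoxC_KO_TNF (SD, n = 3 each), with exact permutation p = 0.6 and p = 0.1. By number, Sox12 without TNF was 352, 342 and 162 in control and 230, 194 and 259 in SoxC_KO, higher for number 3. Over all genes none of these passed limma's Benjamini-Hochberg adjustment, Sox4 having a log2 change of -1.62 (SE 0.48, adjusted p = 0.999) without TNF and -1.30 (SE 0.48, adjusted p = 0.997) with TNF. Sox4 lies on the minus strand of chromosome 13 (mm10, 28948919 to 28953713) and overlaps Gm26735, a gene on the plus strand (28943048 to 28951671) named here after its values were seen. Gm26735 was listed at 0 in control replicates 1 and 2 and control_TNF replicate 2, the 3 libraries with the highest Sox4 values (4238, 4143 and 3646), so the 2 genes' reads may not be separable and both levels are uncertain. Reads outside the part that Cre removes, which the labels do not give, would not check the knockout.

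**Figure D2:**
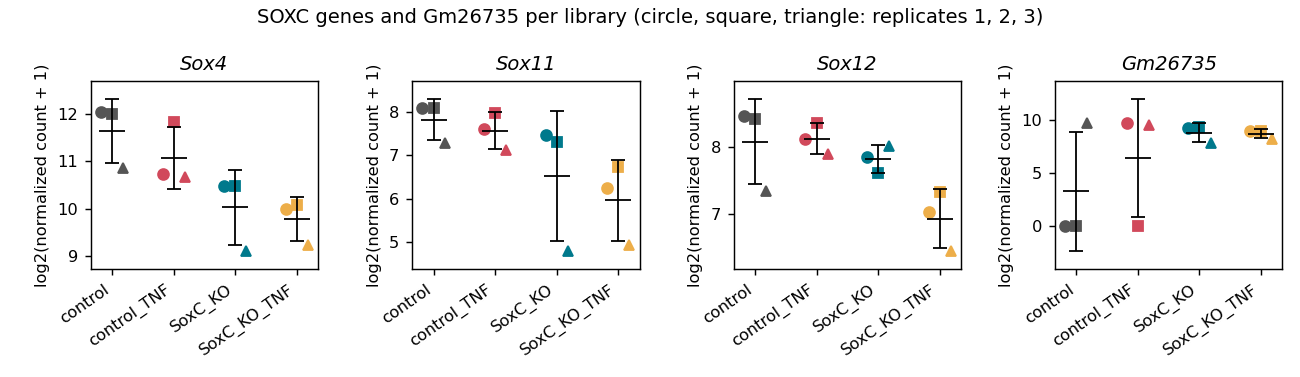
log2(normalized count + 1) of Sox4, Sox11, Sox12 and Gm26735 in each library, by group, with black bars for the mean and SD of 3 libraries. Sox4 in the 6 knockout libraries lies below that in the 6 control libraries, and Gm26735 is at 0 in 3 control libraries.

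TNF raised chemokines, cytokines and matrix-degrading proteases in control cells. Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine that attracts T cells and monocytes, rose from 236 ± 44.0 to 2307 ± 473 normalized counts (SD, n = 3; log2 change 3.28, SE 0.27, limma adjusted p = 0.0012). Mmp9 (chromosome 2, 164940780 to 164955850), a gelatinase, rose from 325 ± 52.2 to 2830 ± 892 (SD, n = 3; log2 change 3.08, SE 0.33, limma adjusted p = 0.00429). Wfdc18 rose by 3.65 on the log2 scale, Ccl3 by 3.16, Gpr84 by 2.65, Calb2 by 2.64, the granulocyte growth factor Csf3 by 2.63, Ccl17 by 2.56, the stromelysin Mmp10 by 2.41 and Slc36a2 by 2.32. Galnt9 (chromosome 5, 110544355 to 110621380) fell from 148 ± 21.1 to 25.4 ± 0.414 (SD, n = 3; log2 change -2.48). The other genes that fell were Clca3a2 (-1.40), Scara5 (-1.24), Arsi (-1.24), Fhl1 (-1.04) and Prss23os (-0.99), the last named as an opposite-strand gene whose reads may not be separable from those of Prss23. In all, 52 genes rose and 6 fell among 18139 (limma, Benjamini-Hochberg adjusted p under 0.05).

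Of the fixed lists, 9 were higher and 2 lower with TNF in control cells by camera. Of 23 chemokines tested, 8 rose and 15 did not pass (14 rose when adjusted over the list alone; camera adjusted p = 3.2e-32), with Cx3cl1 at 2.20 beside Ccl5. Of 24 genes of the NF-kB pathway, 2 rose, Traf1 (log2 change 2.03) and Tnip1 (1.27), and 12 did so adjusted over the list alone (camera adjusted p = 2.7e-20). Of 26 cytokines and growth factors 4 rose, Csf3, Tslp (2.08), Il1a (1.86) and Tnf itself (1.61), and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.3e-10). Of 26 matrix proteases and inhibitors 4 rose, Mmp9, Mmp10, Serpinb2 (1.85) and the collagenase Mmp13 (1.35), and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.67e-06). The interferon list (1 of 36 rose, Gbp2, log2 change 1.28; 2 adjusted over the list alone) and the prostaglandin and nitric oxide list (0 of 10 passed; 4 rose and 1 fell adjusted over the list alone) were also higher. These 6 calls held with an estimated correlation, at adjusted p = 0.0027 to 0.0372. The lists for antigen presentation, complement, antioxidant genes, contractile genes and osteoblast markers, the last 2 lower, passed camera (0 members passing in each over all genes) but not with an estimated correlation (adjusted p = 0.0916, 0.0814, 0.141, 0.0916 and 0.0916). Vcam1, an adhesion molecule, rose by 0.95 and the oxygen-sensing enzyme Egln3 1.99-fold, while their lists did not pass (camera adjusted p = 0.807 and 0.227).

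With replicate number as a block, 310 genes passed in control cells (214 up and 96 down), including all 58, and the extracellular matrix, cell cycle and neutrophil marker lists also passed camera (adjusted p = 0.00028, 0.0033 and 0.00094, and 0.342, 0.085 and 0.106 with an estimated correlation). With both the block and an estimated correlation 3 lists passed, NF-kB, chemokines and prostaglandin (adjusted p = 0.0436, 0.0452 and 0.0452), and the cytokine, protease and interferon lists did not (adjusted p = 0.0514, 0.086 and 0.121). The block also moved the counts of members. Over all genes 14 chemokines, 12 NF-kB genes, 8 cytokines, 6 proteases (1 fell), 3 interferon genes, 7 antigen presentation genes, 2 complement genes, 3 prostaglandin genes (1 fell) and 2 antioxidant genes rose, 1 contractile and 1 extracellular matrix gene fell, and 0 osteoblast markers and 0 cell cycle genes passed. Of 3 neutrophil markers 2 rose, S100a8 and Camp, named after their values were seen, and of the adhesion and hypoxia lists 3 and 1. Adjusted over the list alone, 16 chemokines (1 fell), 15 NF-kB genes, 13 cytokines (3 fell), 9 proteases (3 fell), 19 interferon, 14 antigen presentation, 7 complement (1 fell), 6 prostaglandin (2 fell), 6 antioxidant, 4 adhesion and 2 hypoxia genes and 2 neutrophil markers rose, and 4 contractile genes, 3 osteoblast markers and 6 extracellular matrix genes fell (1 of the last list rose). A fit to only these 6 libraries called 0 genes, and 5 genes were called without control_TNF replicate 1, all among the 58, and 9 to 35 without each of 9 other libraries. Of counts chosen after the data were seen, 15 genes passed without the 2 libraries with liver transcripts, 12 of them among the 58, and 267 without the 4 libraries numbered 3, 55 of them among the 58.

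TNF in knockout cells also raised chemokines, cytokines and matrix proteases. Ccl5 rose from 322 ± 81.7 to 1987 ± 466 (SD, n = 3; log2 change 2.63, SE 0.27, limma adjusted p = 0.00198) and Mmp9 from 372 ± 87.4 to 2545 ± 910 (SD, n = 3; log2 change 2.72, SE 0.33, limma adjusted p = 0.00626). Mmp1b, whose reads may be shared with its close copy Mmp1a, rose 11.3-fold, and 5.98-fold, still called, without SoxC_KO replicate 3. On the log2 scale Wfdc18 rose by 3.05, Gpr84 by 2.62, Il1a by 2.49, Serpinb2 by 2.48, Tslp by 2.40, Acod1, the enzyme that makes itaconate, by 2.37 and the growth factor Csf2 by 2.29. Galnt9 fell from 159 ± 21.1 to 17.5 ± 2.18 (SD, n = 3; log2 change -3.11). The adrenergic receptor Adra1d (-1.96), Crocc2 (-1.83), Dio3 (-1.79), which inactivates thyroid hormone, Arsi (-1.46), Lingo3 (-1.45), Scara5 (-1.44) and Lmod1 (-1.20) also fell. In all 44 genes rose and 9 fell among 18139 (limma, Benjamini-Hochberg adjusted p under 0.05).

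Camera called 7 lists higher and 4 lower with TNF in knockout cells. Of 23 chemokines 6 rose (14 up and 1 down adjusted over the list alone; camera adjusted p = 3.1e-17), among them Cx3cl1 (1.84), Ccl9 (1.58) and Cxcl10 (1.56). Of 24 NF-kB pathway genes 3 rose, Traf1 (1.61) and the feedback genes Tnfaip3 (1.59) and Birc3 (1.56), with 9 up and 1 down adjusted over the list alone (camera adjusted p = 2.1e-09). Of 26 cytokines and growth factors 4 rose, including Bmp2 (2.84-fold), and of 26 proteases and inhibitors 3 rose, including Mmp13 (1.74), with 9 and 8 up adjusted over the list alone. These lists, the prostaglandin list (0 of 10 passed; 5 up adjusted over the list alone) and the contractile list (1 of 12 fell, Lmod1; 3 adjusted over the list alone) held with an estimated correlation at adjusted p = 0.0057 to 0.0395. The interferon list (1 of 36 rose, Gbp2, log2 change 1.51; 4 adjusted over the list alone), antioxidant genes, reported SOXC targets, chondrocyte and osteoblast markers did not (adjusted p = 0.064, 0.427, 0.141, 0.537 and 0.117 with an estimated correlation), the last 3 being lower.

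With the block, 505 genes passed in knockout cells (323 up and 182 down), including all 53. The extracellular matrix, antigen presentation and stress response lists then passed camera (adjusted p = 0.00067, 0.0337 and 0.0343, and 0.352, 0.629 and 0.531 with an estimated correlation) and the reported SOXC targets did not (adjusted p = 0.0517). With the block, 0 of the 31 lists passed with an estimated correlation. Over all genes 12 chemokines, 10 NF-kB genes (1 fell), 9 cytokines, 8 proteases (1 fell), 7 interferon, 6 prostaglandin and 4 antioxidant genes then rose, 4 contractile genes, 2 chondrocyte and 2 osteoblast markers and 3 extracellular matrix genes fell (1 of the last list rose), 1 stress response gene fell, and 0 antigen presentation genes and 0 reported SOXC targets passed. Adjusted over the list alone, 15 chemokines (1 fell), 15 NF-kB genes (2 fell), 14 cytokines (1 fell), 10 proteases (2 fell), 20 interferon, 6 prostaglandin and 6 antioxidant genes and 1 antigen presentation gene rose, and 9 contractile genes, 3 reported SOXC targets, 2 chondrocyte and 2 osteoblast markers, 2 stress response genes and 11 extracellular matrix genes fell (2 of the last list rose). A fit to only these 6 libraries called 3 genes, Tslp, Galnt9 and Gm16439, the last named after its values were seen, and 14 genes were called without SoxC_KO_TNF replicate 1, 13 of them among the 53, and 19, 29, 19 and 22 without SoxC_KO replicates 1 and 2 and SoxC_KO_TNF replicates 2 and 3. Without the 2 libraries with liver transcripts 10 genes passed, 6 of them among the 53, and without the 4 libraries numbered 3, 186, 49 of them among the 53.

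**Figure D3:**
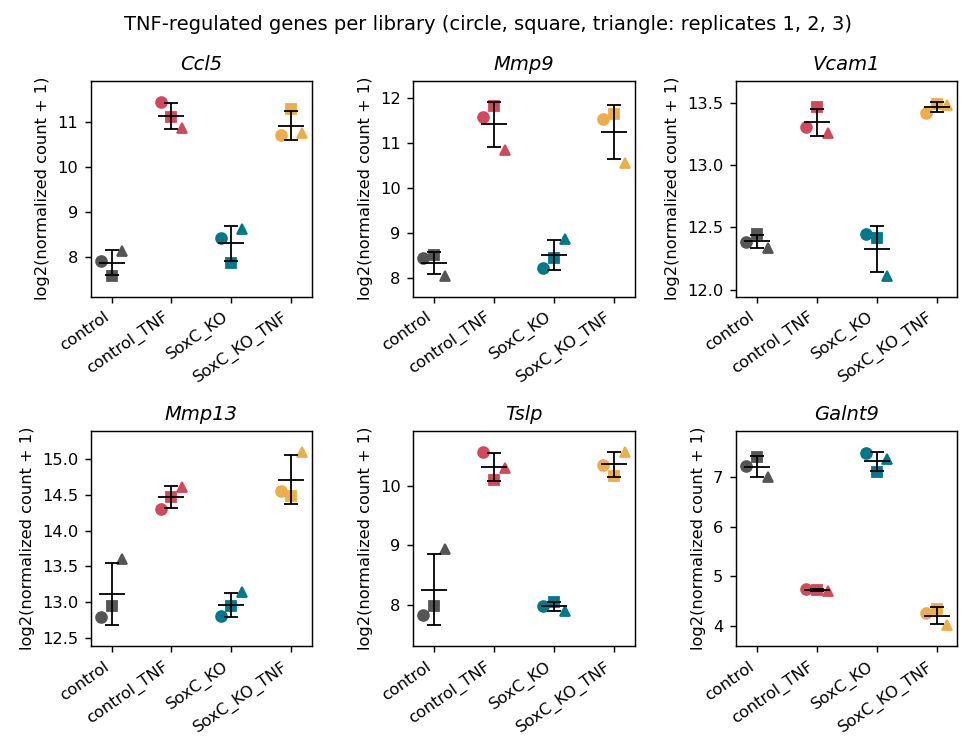
log2(normalized count + 1) of 6 genes called with TNF in each library, by group, with black bars for the mean and SD of 3 libraries. Ccl5, Mmp9, Vcam1, Mmp13 and Tslp are higher and Galnt9 is lower with TNF in both control and knockout cells.

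The 2 TNF responses share no library, but both used the same variance estimate per gene from all 12 libraries. A gene with a small estimate is favoured in both, so the overlap given for independent lists is a low baseline. Of the genes that rose, 30 were called in both (52 and 44), where independent lists would share 0.126, and of those that fell 3 were called in both (6 and 9), where independent lists would share 0.00298. All 58 genes called in control cells had a log2 change of the same sign in knockout cells, whether or not they passed there. For the average of both responses 159 genes rose and 53 fell (limma, adjusted p under 0.05). In 1 simulated draw 11.2% of the calls for this average were false. That draw lacked the shared difference of the libraries numbered 3, so this rate may not hold for the real calls. Across these 212 genes, which are not independent replicates and were selected on this average, the log2 changes correlated at Pearson r = 0.938 (Spearman rho 0.865). Across all 18139 genes tested the correlation was r = 0.153 (Spearman rho -0.0327). With replicate number as a block the average called 941 genes, 546 up and 395 down, including all 212. It called 118, 127, 131 and 139 without control replicates 1 and 2, control_TNF replicate 1 and SoxC_KO_TNF replicate 2 in turn. Without the 2 libraries with liver transcripts 92 passed, 84 of them among the 212, and without the 4 numbered 3, 653, 203 of them among the 212.

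**Figure D4:**
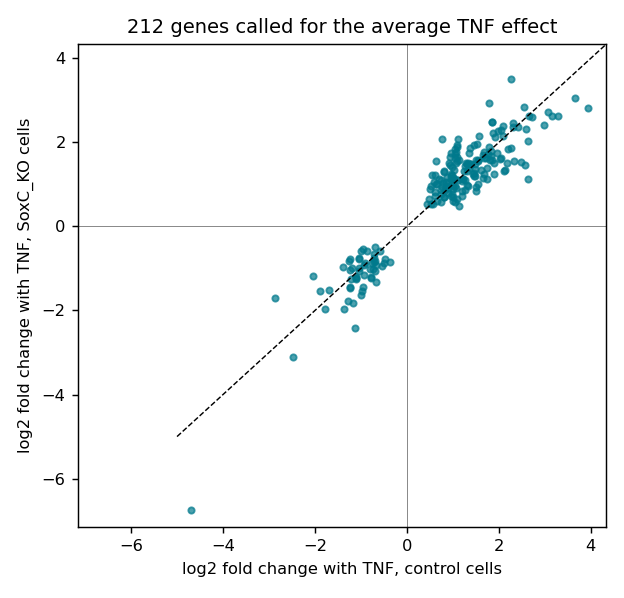
log2 fold change with TNF in control cells (x) against knockout cells (y) for the 212 genes called for the average TNF effect, 1 point per gene, with the dashed line marking equal changes. Across these genes, selected for their average, r = 0.938, against r = 0.153 across all 18139 genes tested.

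Knockout without TNF gave no called gene (limma, 0 of 18139; 176 at unadjusted p under 0.05 where 907 would be expected by chance). The SOXC family list was lower by camera (adjusted p = 0.00229), with Sox4 the 1 of 3 members that fell adjusted over the list alone, and Sox11 and Sox12 had log2 changes of -1.29 (-0.43 without SoxC_KO replicate 3) and -0.25. The chemokine, antigen presentation, complement and glycolysis lists were higher (adjusted p = 0.00623, 0.00181, 0.00823 and 0.0291), with 0 members passing in each, over all genes or adjusted over the list alone. With an estimated correlation all 5 lists had adjusted p = 0.647. With the block 0 genes passed (826 at unadjusted p under 0.05), 2 SOXC family members fell adjusted over the list alone, and the stress response and macrophage marker lists also passed camera (adjusted p = 0.046 and 0.0382, and 0.744 for both with an estimated correlation).

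Knockout with TNF also gave no called gene, without or with the block (limma, 0 of 18139). Without it 233 genes, and with it 1160, had unadjusted p under 0.05, where 907 would be expected by chance. These numbers did not pass the pairing cutoff. Counts under the expected one without the block, here and without TNF, are no evidence that knockout changed nothing. Without the block the SOXC family list was lower (camera adjusted p = 4.81e-06, and 0.113 with an estimated correlation). All 3 members fell adjusted over the list alone, with log2 changes of -1.30 for Sox4, -1.60 for Sox11 and -1.19 for Sox12. Of 5 reported SOXC targets 2 fell adjusted over the list alone and 0 over all genes, and the list was lower (camera adjusted p = 3.65e-05, and 0.0412 with an estimated correlation). With the block and an estimated correlation the target list no longer passed and the SOXC family list did. Here too the numbers did not pass the pairing cutoff. Antigen presentation and contractile genes were lower, and endothelial and skeletal muscle markers higher (camera adjusted p = 0.00932, 0.0235, 0.0235 and 0.0292), none with an estimated correlation (adjusted p = 0.789, 0.56, 0.168 and 0.481). The muscle myosin Myh4, named after its values were seen, stood at 188 in SoxC_KO replicate 1 and 277 in SoxC_KO_TNF replicate 1, and at 13.3 or less in the other 10 libraries. Since no gene was called lower after knockout, an overlap with the 52 TNF-induced genes could not be compared with chance.

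The interaction asks directly whether the TNF response differed between knockout and control cells. No gene passed, without or with the block (limma, 0 of 18139). Without it 273 genes, and with it 3123, had unadjusted p under 0.05, where 907 would be expected by chance. The replicate numbers did not pass the pairing cutoff in every comparison. Without the block the smallest p-values belonged to Entpd1, Fmn2, Dus4l, Chn1 and Hist1h2bq, with interactions of 1.10, 1.34, 1.29, 0.77 and 0.72 on the log2 scale. In the other direction they belonged to Lingo3, Egfl8, Cenps, Rusc1 and Calb2, with -1.26, -1.41, -1.24, -0.75 and -1.52. All had limma adjusted p = 0.884. Hist1h2bq belongs to a family of near-identical genes, so its reads are uncertain. For Ccl5 and Mmp9 the TNF effects of 3.28 and 3.08 in control cells stood beside 2.63 and 2.72 in knockout cells, interactions of -0.65 (SE 0.37) and -0.36 (SE 0.47). The median 95% interval of an interaction reached 1.14 on the log2 scale to either side of the estimate. In simulated data this model, which has no replicate block, recovered 4% of 2-fold and 30% of 4-fold interactions in genes averaging at least 50 normalized counts. Differences of these sizes were thus mostly not detectable with it. The antigen presentation list was lower (camera adjusted p = 0.000506, and 0.716 with an estimated correlation), with a median of -0.58 and 0 of 18 members passing, over all genes or adjusted over the list alone.

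Among the 145 genes called for the average TNF effect with a size of at least 1 on the log2 scale, 44.1% had a smaller response in knockout cells, 46.2% of the 117 induced and 35.7% of the 28 repressed. In 100 assignments of genotype within treatment, the real one included, 49 lay at least as far from an even split (permutation p = 0.49), with shares from 30.3% to 69.7%. Of the 41 that, like the real one, kept 1 library numbered 3 in each arm of both treatments, 27 did, with the same range. Of the 145, 0 had an interaction passing limma's adjustment in either direction, and 36 had a 95% interval within -1 to 1. The share was 64.1% without control replicate 3 and 60.4% without the 4 libraries numbered 3, both within the range of those assignments.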

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

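The counts of other splits and the comparison with the libraries numbered 3 were chosen after the result was seen. The interaction was negative for the antigen presentation list, a difference between the TNF responses of the 2 genotypes (camera adjusted p = 0.000506, 0.716 with an estimated correlation, fry adjusted p = 0.745). Of the 100 splits by genotype within treatment, 95 gave at least 1 list, with up to 16 in another split, so chance is not excluded. Of the 100, 59 put the libraries numbered 3 unevenly between the arms of a treatment. Among the 41 that kept 1 of them in each arm of both treatments, as the real split does, 36 gave at least 1 list, with up to 8 in another. The same list was higher in the libraries numbered 3 (13 of 18 genes higher and 1 lower; camera adjusted p = 0.00034, and 0.686 with an estimated correlation).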

How the results depend on the processing

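The fixed alternatives were chosen before the data were examined, and those marked as added after. Count models on recovered reads were not run, since whole reads were not recovered. Where no cause is given it was not tested. For TNF in control cells the 58 calls became 35 with no filter, 0 with only the 2 groups compared and 310 with the replicate block. Library weights called 11586, but gave control_TNF replicate 1 a weight of 103, so these calls rest on 1 library. For TNF in knockout cells the 53 calls became 3, 505 and 1268 with only the 2 groups, the replicate block and weights, and for the average TNF effect the 212 became 941 with the replicate block and 6726 with weights. All calls of these 3 comparisons remained with the replicate block. Weights called 15 genes for knockout without TNF, 9698 for knockout with TNF, 5656 for the interaction, 500 for the average knockout effect and 3326 TNF-induced genes lower after knockout, where the other fixed alternatives gave 0 except the replicate block, with 1 for the average knockout effect. For knockout with TNF, the block moved the SOXC targets from adjusted p = 0.0412 to 0.275 and the SOXC family from 0.113 to 0.0491 (camera, estimated correlation). For the interaction the block gave 3123 genes at unadjusted p under 0.05 (273 without it, 907 expected by chance) and 0 called (smallest limma adjusted p = 0.284), in a fit that recovered 29% of 2-fold and 84% of 4-fold simulated interactions. For the average TNF effect the block added the SOXC family, cell cycle and neutrophil lists (camera adjusted p = 0.0434, 0.000412 and 0.00143). With an estimated correlation it added the cell cycle list (adjusted p = 0.0492) and ended the protease, interferon, contractile and osteoblast calls (0.0681, 0.0814, 0.084 and 0.0681). Paired values for knockout with TNF, the interaction and the average knockout effect come from numbers that did not pass the pairing cutoff in every comparison. Of the 12 libraries, 4 did not correlate best with their own number (control replicate 1, SoxC_KO replicate 1 and SoxC_KO_TNF replicates 1 and 2). In the paired comparisons the block changed no camera call beyond those given here and with the results and ended no call of a gene, while genes named for 1 TNF comparison, such as Csf3 and Mmp10 in control cells, also passed in the other.

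The next counts are for TNF in control cells, in knockout cells and on average, in that order. Of the alternatives added after seeing the data, the length and GC correction gave 89, 90 and 386 genes, and with the replicate block 688, 771 and 1538. A term for the libraries numbered 3 gave 361, 674 and 1076. Leaving these 4 out gave 267, 186 and 653, while leaving out the 2 libraries with liver transcripts gave 15, 10 and 92. Fewer libraries thus did not always mean fewer calls. The block with length and GC correction called 1 gene, Sox4, for knockout without TNF, with TNF and on average. The number 3 term called 1 gene, Sox4, on average. Leaving out the libraries numbered 3 called 1 gene, Gm26602, for each of the 3, at log2 changes of 6.87, 6.77 and 6.82 (this gene and Fam219aos are named after their values were seen). Without the liver libraries 1 gene, Fam219aos, was called for knockout with TNF and for the interaction, at -5.45 and -6.13. Neither Gm26602 nor Fam219aos was called with all 12 libraries, and neither is read as a knockout effect. Sox4 passed at -1.55 with weights and -1.52 with block and correction without TNF, and at -0.69 and -1.38 with TNF, where weights also called Sox11 (-1.01) and Sox12 (-0.87). The share of reduced responses was 64.9% with weights, 57.4% and 57.0% with the correction without and with the block, and 60.4% without the libraries numbered 3.

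Camera lists became 6, 6, 0, 1, 0, 8 and 3 with an estimated correlation, for TNF in control and knockout cells, knockout without and with TNF, interaction, average TNF and average knockout (11, 11, 5, 6, 1, 13 and 7 with the preset), and fry gave 0, 2, 0 and 0 for knockout without and with TNF, the interaction and the average knockout. No filter gave 2 lists for knockout without TNF and 4 on average. Without the libraries numbered 3 there were 8 for knockout without TNF and 3 for the interaction, and without the liver libraries 17 for TNF in knockout cells, 3 for the interaction and 4 for the average knockout.

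Leaving out 1 library gave 5 to 84 genes for TNF in control cells, moving the count over 1.5 times without control replicates 1 (9) and 2 (11), control_TNF replicates 1 (5), 2 (14) and 3 (22), SoxC_KO replicates 1 (31) and 2 (34) and SoxC_KO_TNF replicates 1 (28), 2 (28) and 3 (35). For TNF in knockout cells it gave 14 to 55, moving without SoxC_KO replicates 1 (19) and 2 (29) and SoxC_KO_TNF replicates 1 (14), 2 (19) and 3 (22), and for the average 118 to 253, moving without control replicates 1 (118) and 2 (127), control_TNF replicate 1 (131) and SoxC_KO_TNF replicate 2 (139). Both knockout comparisons and the interaction stayed at 0. The share ranged from 39.8% to 64.1%, the latter without control replicate 3. Lists ranged from 7 to 17 for TNF in knockout cells, 3 to 10 and 2 to 10 for knockout without and with TNF, 1 to 7 for the interaction and 2 to 13 for the average knockout. Of changes in sign, all in SOXC genes, Sox12 with TNF in control cells (0.05) was -0.28 with weights, -0.20 without the libraries numbered 3, -0.067 without the liver libraries and -0.32 to 0.24 leaving out 1 library. Leaving out 1 library, Sox4 with TNF in knockout cells ranged from -0.71 to 0.017, Sox4 in the interaction from -0.15 to 0.70 and Sox11 in the interaction from -1.16 to 0.22. Of the values of single named genes counted under the alternatives, 1692 kept direction and side of the threshold, 491 lost significance, 13 gained it and 10 changed sign. Values passing in neither fit count as kept. Genes named only as the highest member of a list were left out, as were the SOXC genes in both knockout comparisons.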

Other observations

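All tests in this part were chosen after the results were seen. The mean of both knockout effects called 0 genes without the block, and 1 with it. The numbers did not pass the pairing cutoff in every comparison. The called gene was Sox4, with a log2 change of -1.46 (SE 0.16, limma adjusted p = 0.0146). The SOXC family and reported SOXC target lists were lower on this average (camera adjusted p = 8.2e-14 and 4.0e-08, and 0.0103 and 0.0092 with an estimated correlation). Tead2, a TEAD transcription factor on the second list, averaged -0.57 (SE 0.21) and Mex3a -0.74 (SE 0.20), both named after their values were seen and neither passing.

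The 4 libraries numbered 3 stood apart from the other 8 in all groups. A limma term for them called 5635 genes lower and 4832 higher (adjusted p under 0.05). All 3 SOXC genes were among the lower ones (median log2 difference -0.99), while their list did not pass camera (adjusted p = 0.198). Cell cycle genes were lower (23 of 30 fell, 2 rose; camera adjusted p = 3.2e-08, and 0.0081 with an estimated correlation), with Mki67 at -3.74 and Top2a at -2.34 on the log2 scale, and extracellular matrix genes were lower by camera (25 of 33 fell, 1 rose; adjusted p = 6.5e-09, and 0.365 with an estimated correlation). Chondrocyte markers were lower (4 of 7 fell), and macrophage markers (10 of 13 rose, 1 fell), antigen presentation genes (13 of 18 rose, 1 fell) and antioxidant genes (8 of 15 rose, 1 fell) higher, by camera (adjusted p = 0.0499, 0.0040, 0.00034 and 0.0092) but not with an estimated correlation (adjusted p = 0.50, 0.529, 0.686 and 0.529). The macrophage marker Lyz2 (1.45), S100a8 (2.02), Ccl8 (1.54), the stress gene Ddit3 (1.64) and the cell cycle inhibitor Cdkn2a (1.47), all named with Mki67 and Top2a after their values were seen, were higher.

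Across genes the difference of the libraries numbered 3 ran with shorter transcripts (Spearman rho -0.37) and higher GC content (0.45), but after each library's trend with both was removed the lowest correlation of 2 libraries numbered 3 was still 0.477, which argues against that trend as the whole cause. Depth stays open. The rough estimates were 10.8, 8.43 and 8.61 M read pairs in the libraries numbered 3 of control, control_TNF and SoxC_KO, each the lowest of its group, and 13.0 M in that of SoxC_KO_TNF, the highest of its group, with a median of 9.70 M against 11.0 M for all 12. The shallowest of all 12, SoxC_KO_TNF replicate 1 (8.14 M), lay at -52.7 on the first principal component, the end opposite the libraries numbered 3, which goes against depth but as 1 library does not exclude it. A difference in culture, cell makeup, RNA handling or library preparation stays open, and no biological explanation was tested.

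Gm26735 was at 0 in 3 control libraries and averaged 571 in the other 9. A candidate explanation is that reads were assigned differently between libraries. It predicts more genes at 0 in exactly these 3 libraries and at 50 or more in the other 9 than in any other of the 220 sets of 3. There were 2, Gm26735 and Gm26527, which overlaps Arsb, both named after their values were seen, against 1 in another set, too few to decide. Added together, Sox4 and Gm26735 kept an average knockout effect of -1.20 on the log2 scale with the block (95% interval -1.51 to -0.89, and -1.81 to -0.60 without it). This argues against Sox4 reads counted for Gm26735 as the whole cause of the lower Sox4 values. Reads counted for neither gene would be missing from the sum, so it cannot exclude their loss as a cause. Where Gm26735 was counted, Sox4 was 1857 in control replicate 3 and 1697 and 1626 in control_TNF replicates 1 and 3. The knockout libraries, all with Gm26735 counted, held 548 to 1433.

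Liver transcripts were seen in control_TNF replicate 2 and SoxC_KO_TNF replicate 1. Albumin (Alb) stood at 382 and 2690 normalized counts there and at 7.54 or less elsewhere, and Apoa2 at 44.1 and 258, both named after their values were seen. Of 24 liver markers listed after this was noticed, 19 and 24 reached 10 in these libraries, and at most 8 did in the others, 4 of the 24 being at 10 or more in most other libraries. RNA from liver in these 2 libraries may be the source, but the markers and the threshold of 12 were set after these transcripts were seen, so the lower count of 19 does not test it and the source stays open. An effect of TNF is argued against, since the other 4 libraries with TNF held at most 5 of the markers.

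Other splits of the same libraries were counted. With 3 libraries against 3, 10 splits are too few for a share under 0.05. TNF in control cells gave 58 genes and 11 lists against at most 4 and 9 in another split, and TNF in knockout cells 53 and 11 against 0 and 10 (1 split, the real one, reached each of these 4 values). Among the 4 splits that part all same-numbered pairs, the highest others were 0 genes and 7 lists in control cells and 0 and 9 in knockout cells. Knockout without TNF gave 0 genes and 5 lists against 0 and 8 (4 splits reached 5 lists), and knockout with TNF 0 and 6 against 2 and 7 (3 splits reached 6 lists). A count of 0 genes is reached by all 10 splits by construction, so it tests nothing. For the average TNF effect 2 of the 100 splits drawn, the real one included, gave as many genes as the real 212, a share under 0.05. Not every possible split was drawn, and the libraries numbered 3 are not exchangeable with the rest, so this share holds only for the splits drawn. As many lists as the real 13 came from 6 splits, with 15 in another, so for lists chance is not excluded. The other split, with 5119 genes, set all 4 libraries numbered 3 in 1 arm, which points to a structure of the samples, and the blocked count was 941. The interaction and the average knockout effect called 0 genes, which all 100 splits reach by construction, so these counts say nothing of chance. The highest other counts, 7831 and 4426 genes, came from splits that set the libraries numbered 3 along the contrast, and among the 41 splits that kept 1 of them in each arm of both treatments the highest others were 0 and 1. The average knockout effect gave 7 lists, which 20 of the 100 splits reached, with 12 in another, so chance is not excluded. Among those 41 splits 2 reached 7 lists, the real one included, with 8 in the other. That share is just under 0.05, so the answer depends on which splits are counted, and chance stays open.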
